A study of Mus musculus with 16 samples.

How the data were processed

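The data are 16 peak lists from ATAC-seq of lineage-depleted mouse bone marrow, with 4 libraries in each of 4 groups (control or diabetic, baseline or IL-1β). Per the labels' protocols, nuclei of 50000 cells per replicate were tagged with Tn5, fragments above 1200 bp were removed and libraries were sequenced with 50-bp single reads. Per the submitters' processing notes the tools were Trim Galore 1.8, FastQC 0.11.3, Bowtie2 2.2.6, MACS2 2.1.1, DiffBind 2.4.8 and edgeR, with the build mm10; the notes give no role or order. Whether reads were shifted for the Tn5 insertion and whether duplicates were removed is not given in the sources used here. Such steps move summits by a few bases and change reads per summit.

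Each deposited list belongs to 1 library. Its lines give a peak's position, a score, a fold enrichment at the summit, a −log10 p, a −log10 q and the summit's place, all as the authors' peak caller wrote them. The deposited score is the whole part of 10 times the −log10 q. The deposited fold is a ratio over the local background. The lowest deposited −log10 q was 1.30, a q of 0.0500, and the narrowest peak spanned 147 bp. Peaks with several summits stand on several lines, which were joined for counting. Positions are printed 1-based. Scores were not compared between libraries, and −log10 q served only to filter lists and to order named regions.

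Peaks of all lists were merged where they overlapped or touched by at least 1 bp, and regions called in at least 2 libraries were kept. Genes came from RefSeq's table for GRCm38.p6, whose main chromosomes have the coordinates of mm10, with 21883 protein-coding genes. That table has no strand and no genome was used here, so the planned share of summits at transcription start sites became the share within 1 kb of either gene end. The nearest start site became the nearest gene body within 50 kb, and the 18 planned motif tests were not run. A region counted for a gene when it lay within 10 kb of its body, for genes with at least 3 such regions. Assignment rests on position alone.

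Tests fixed before the data were examined were two-sided exact permutation tests for values per library, per gene and per list (4900 label assignments within phenotype for IL-1β, smallest p 0.000408; 70 for 4 libraries against 4, smallest p 0.0286), and Fisher's exact test per region, each with Benjamini-Hochberg adjustment at 0.05. Regions called in 4 of 4 libraries of a group and 0 of 4 of the other were counted, without a test per region. The 20 gene lists and the rule for named genes were fixed with them: the 8 gained and 8 lost regions with the largest difference in calling libraries, ties by mean −log10 q, 3 members of each list with the largest change, and genes past the gene test. Of 333 list symbols 332 matched a protein-coding gene. Streptozotocin was given to the diabetic mice only, and p-values rest on 4 mouse samples per phenotype.

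Because those tests called nothing, reads were then recovered from the lists, a step chosen after seeing the data. MACS2 writes the fold as (n + 1) / (λ + 1) and p from a Poisson distribution of mean λ, so that whole reads n and background λ follow from both. A summit counted as recovered when its −log10 p was met within 0.001, which held for 99.999% to 100% of summits per library. For the 24955 regions called in all 16 libraries, log2 of the highest summit was scaled to equal medians and fitted in limma with 4 group means and a trended variance. This keeps out regions that lost or gained a call, which the tests on calls cover. Named regions, by a rule also set after seeing the data, are the 12 largest rises and falls past the threshold, at most 1 per gene, and list members past it. Some items that these rules name are not reported here. Gene lists were tested with camera, with a preset correlation of 0.01 and with an estimated one. The alternatives were cyclic loess, scaling by background, regions called in at least 12 libraries, a mouse block, each library left out in turn, and mice left out. Means of 4 marker lists were also tested by exact sign flips of the differences within mice. In a first look, regions called in all or at least 12 libraries were combined with median or loess scaling, 4 configurations in all, and the one reported was chosen after the counts of all 4 had been seen.

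The portions of a mouse sample carry the same number, and the series design says that each sample was split, so the numbers pair libraries within a phenotype. Deviations of both portions from their group means correlated, over shared regions, by 0.42, 0.36, 0.01 and 0.07 in control mice 1 to 4 and by 0.40, 0.19, -0.04 and 0.33 in diabetic mice 1 to 4. Equal numbers across phenotypes name different animals.

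Depth is known only through background, 0.856 to 1.71 reads per window, and summit reads. The computations were tested on simulated data. Drawn reads were returned for 99.4% of 4987 simulated summits. Among 24955 simulated regions, limma recovered 68 of 100 regions changed 1.5-fold and 99 of 100 changed 2-fold for IL-1β against baseline, and 20 and 88 of 100 for diabetic against control at baseline. Fisher's test on 83972 regions recovered 0 of 200 regions set to 8 against 0, and 400 of 400. The permutation test per gene, run on 11000 simulated genes, recovered 0 of 200 genes shifted by 1 SD and 134 of 200 shifted by 3 SD. The software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.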

Results

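Chromatin accessibility was profiled by ATAC-seq, in which the Tn5 transposase cuts and tags open DNA, in bone marrow cells of male C57Bl/6 mice after depletion of cells carrying CD3, CD4, B220, Ter119 or Gr1. The submitters call these lineage-negative cells haematopoietic stem cells; stem cells are a small part of such a fraction, which also holds committed progenitors. Cells of 4 mouse samples made diabetic with streptozotocin and of 4 control samples were each divided. The baseline portion was lysed at once, and the other portion was cultured for 6 h with 10 ng/mL of interleukin-1β (IL-1β), giving 4 groups of 4 libraries. Stimulation and 6 h of culture therefore always came together, and every difference named after IL-1β is a difference after IL-1β with culture.

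The 16 peak lists held 920021 distinct peaks with 1057251 summits on build mm10. A library held between 37543 peaks (control IL-1β replicate 2) and 72525 peaks (control baseline replicate 3). Peaks of all libraries merged into 102496 regions, of which 83972 were called in at least 2 libraries and 24955 in all 16. Of the 83972 regions, 58.2% overlapped the body of a protein-coding gene and 16.9% lay within 1 kb of a gene end. Background, the lowest expected number of reads per window that the peak caller used, ran from 0.856 to 1.71 reads and stands in for sequencing depth. The median summit over the regions shared by all libraries held 27.0 to 58.0 reads.

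The question of whether IL-1β or diabetes changed the amount of detected open chromatin was addressed with peak number and with the share of summits near gene ends. Baseline libraries held 61699 ± 8759 peaks (SD, n = 8) and IL-1β libraries 53304 ± 9760 (SD, n = 8), a difference of -8395 (two-sided exact permutation test, p = 0.102). The share of summits within 1 kb of a gene end was 26.3% ± 1.95 at baseline and 28.8% ± 3.25 after IL-1β (SD, n = 8 each, exact permutation p = 0.0931). Peaks with a −log10 q of at least 5 alone gave differences of -7827 peaks (exact permutation p = 0.0449) and 3.41 percentage points (exact permutation p = 0.0392). List length enters the gene-end share. The library with the fewest peaks, control IL-1β replicate 2, had the highest share, 34.9%. The library with the most, control baseline replicate 3, had the lowest, 24.3%. The difference in share can therefore not be told apart from that in peak number. Signal over background, the median summit reads of shared regions divided by background reads, was 35.1 ± 5.80 at baseline and 29.3 ± 6.21 after IL-1β (SD, n = 8 each, exact permutation p = 0.0535). That test did not pair the portions of a mouse. The value was lower after IL-1β in every mouse but control mouse 4 (30.2 to 34.5), so a difference within mice is not excluded. Diabetic libraries held 59564 ± 9604 peaks at baseline against 63834 ± 8639 in control libraries (SD, n = 4 each, exact permutation p = 0.571). After IL-1β they held 53624 ± 7624 against 52983 ± 12801 (SD, n = 4 each, exact permutation p = 0.943). The change with IL-1β differed between phenotypes by 4910 peaks (exact permutation p = 0.771). With 4 libraries against 4, the smallest p these tests allow is 0.0286.

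**Figure D1:**
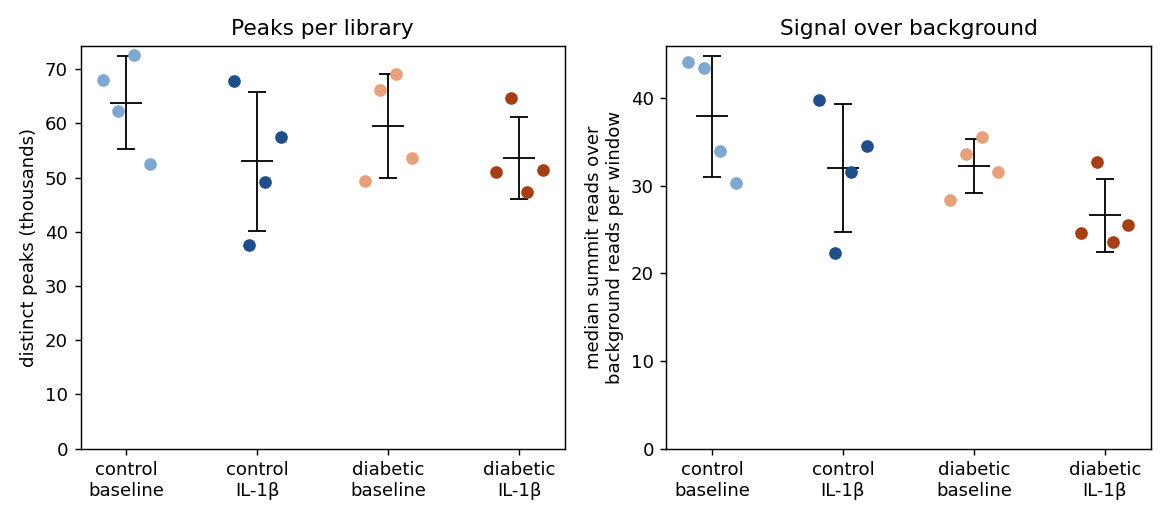
Peaks per library in units of 1000 (left) and signal over background (right) for the 4 groups; points are libraries, horizontal bars the group mean and error bars the SD (n = 4). Control IL-1β replicate 2 held the fewest peaks, 37543, and control baseline replicate 3 the most, 72525.

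The comparison of IL-1β with baseline asked how the stimulus and culture changed chromatin in these progenitors. Reads at the summit of regions called in all 16 libraries rose near Ankrd12, Hspb7 (a small heat shock protein), Msmo1 (an enzyme of cholesterol synthesis), Kcnn4 (a calcium-activated potassium channel) and Slc11a1 (a metal transporter of phagosomes). They fell near Suco, Ssbp2, Dusp6 (a phosphatase acting on ERK kinases) and Tsc22d3 (a glucocorticoid-induced leucine zipper protein). Of 24955 regions, 1603 rose and 848 fell at a Benjamini-Hochberg adjusted p below 0.05 (limma on log2 summit reads). This test was chosen after the tests fixed in advance had called 0 regions, as given below. Values are relative to the median shared region. With libraries scaled by background instead, that median moved by -0.24 on the log2 scale against 0.03, and 203 regions rose while 2343 fell (7.97% higher, against 65.4%). With the mouse as a block, 2400 rose and 1294 fell, and without diabetic baseline replicate 4 the counts were 2787 and 1657.

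The region 3877 bp from Ankrd12 (chromosome 17, 65961439 to 65962212) went from 10.4 ± 2.16 scaled summit reads to 43.0 ± 5.43 (SD, n = 8 each), a log2 change of 2.07 (SE 0.15, limma adjusted p = 1.27e-08). The region 638 bp from Hspb7 (chromosome 4, 141425515 to 141426381) went from 9.84 ± 1.8 to 33.9 ± 8.08 reads (log2 change 1.76, SE 0.15). Within the Msmo1 gene body (chromosome 8, 64726081 to 64726807), reads went from 16.1 ± 4.23 to 44.8 ± 6.42 (log2 change 1.52, SE 0.16). Regions nearest to Kcnn4 (log2 change 1.47), Tram2 (1.38), Slc11a1 (1.35), Grhl1 (1.33, 16738 bp away), Ccdc97 (1.33), Gch1 (1.33), Capg (1.3), Rest (1.28, 13040 bp away) and Gm38664 (1.28, 10880 bp away) followed. Gch1 makes the first enzyme of tetrahydrobiopterin synthesis, Capg caps actin filaments and Rest is a transcriptional repressor. Each of these 12 regions was higher after IL-1β in 8 of 8 mice and stayed past the threshold with background scaling (adjusted p at most 0.000401).

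The largest fall lay 19455 bp from Suco (chromosome 1, 161896054 to 161896529), where reads went from 64.0 ± 6.31 to 20.5 ± 5.17 (SD, n = 8 each) and the log2 value fell by 1.68 (SE 0.13, limma adjusted p = 1.97e-08). A region inside Ssbp2 (chromosome 13, 91509456 to 91509904) fell by 1.47 (SE 0.16) on the log2 scale, and regions at Ppp1r12b, Zfp831 and Vrk1 fell by 1.28, 1.25 and 1.12. The region 30652 bp from Dusp6 went from 61.0 ± 10.6 to 28.4 ± 2.90 reads and fell by 1.09 (SE 0.11). The region 1665 bp from Tsc22d3 (chromosome X, 140537704 to 140538022) went from 49.2 ± 3.01 to 23.7 ± 4.22 reads and fell by 1.07 (SE 0.11). Regions nearest to Tnfsf15 (41316 bp away), Tbc1d10c, Ripor2, Poc1b (16948 bp away) and Fam98b fell by 1.12, 1.11, 1.09, 1.09 and 1.05. The region at Ripor2 was higher after IL-1β in 1 of 8 mice, and the other 11 of these 12 in 0 of 8.

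**Figure D2:**
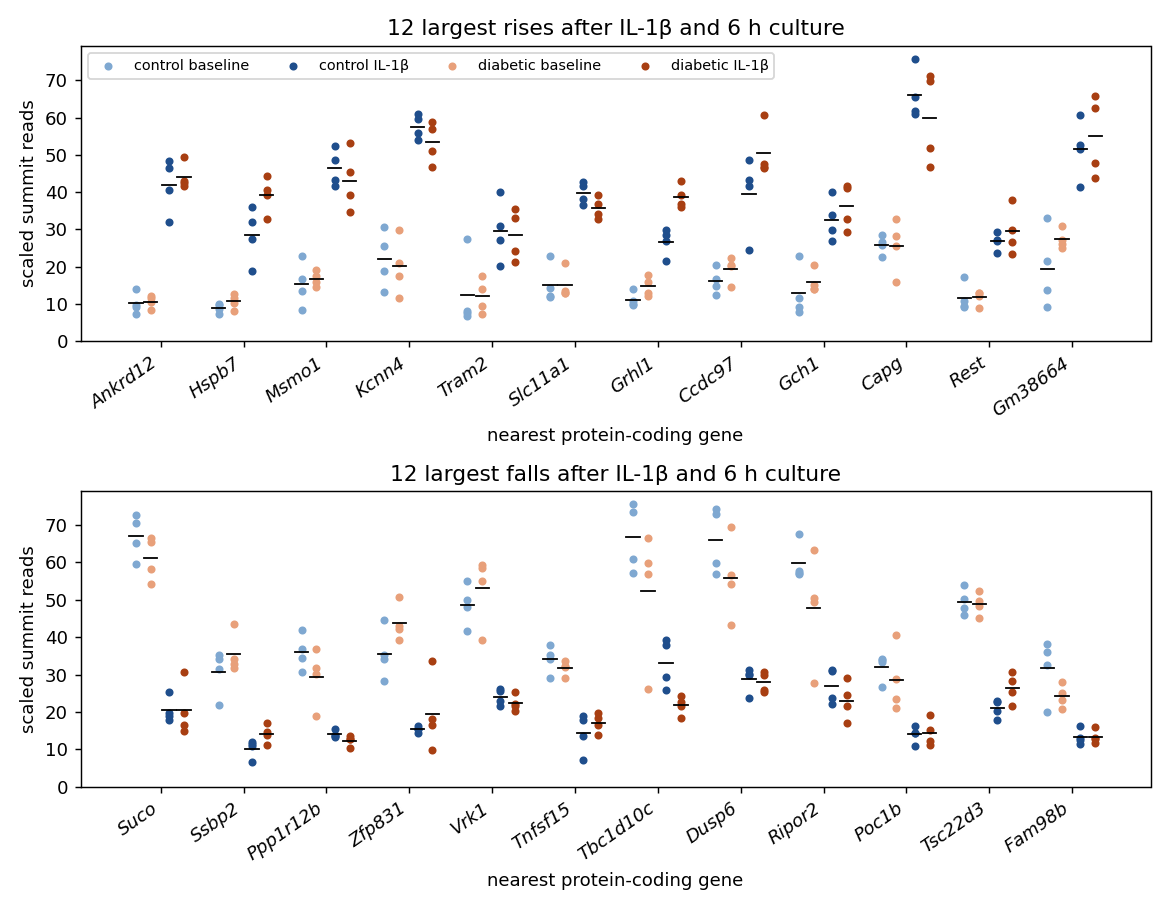
Scaled summit reads (linear axis from 0) at the 12 regions with the largest rise and the 12 with the largest fall after IL-1β and 6 h of culture, by nearest protein-coding gene; points are libraries coloured by group and black bars the group means (n = 4). At Ankrd12 the mean over both phenotypes went from 10.4 to 43.0 reads and at Suco from 64.0 to 20.5.

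Changed regions lay less often at gene ends. Of the 1603 regions that rose, 251 (15.7%, 95% exact binomial interval 13.9 to 17.5) were within 1 kb of a gene end, against 9051 of 22504 uncalled regions (40.2%, Fisher's exact test p = 2.20e-95). Of the 848 that fell, 136 were (16.04%, interval 13.6 to 18.7, Fisher's exact test p = 6.60e-51). Neighbouring regions share reads and cells, so these p-values treat dependent regions as independent. These genes were chosen after their values were seen. Genes with several risen regions among those assigned to them included Irak2, a kinase of IL-1 receptor signalling (6 of 10), Apbb1ip (6 of 9), Plec (5 of 5) and Alox5ap, which supports leukotriene synthesis (4 of 5). Genes with several fallen regions included Adgre5 (4 of 6), Cd44 (3 of 7), Mef2c (3 of 7) and Fosb (3 of 5).

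The NF-κB feedback list holds inhibitors and adaptors that NF-κB itself induces. It also holds the NF-κB subunit genes Nfkb2 and Relb and the IL-1 receptor gene Il1r1, whose risen regions are among those counted. Of 54 shared regions within 10 kb of the 18 listed genes, 15 rose and 2 fell (18 and 2 adjusted over the list alone), with a median log2 change of 0.15. With background scaling 2 rose and 2 fell. The list's median was then -0.12, while the median of all shared regions moved from 0.03 to -0.24. Camera, run on the values scaled to equal medians, gave an adjusted p of 0.00993 for the list. With the estimated correlation between regions, 0.025 against the preset 0.01, the list was not called (camera adjusted p = 0.308). Bcl3, an atypical inhibitor of NF-κB, had 3 risen regions, the largest with a log2 change of 0.75 (SE 0.08, 49.3 ± 6.14 to 82.6 ± 5.32 reads, n = 8 each). Tnip1, a partner of the ubiquitin-editing enzyme made by Tnfaip3, reached 0.81 (SE 0.13), Traf1 0.71 (SE 0.16), Zc3h12a, an RNase that degrades cytokine transcripts, 0.61 (SE 0.11) and Tnfaip3 0.53 (SE 0.12). Both fallen regions were at Irak3, an inhibitor of IL-1 receptor signalling, and fell by 0.55 (SE 0.11) and 0.32 (SE 0.08). Over both phenotypes, NF-κB feedback was the only list of 20 that camera called with the preset correlation, and no list was called with an estimated correlation.

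Cytokine and chemokine genes had 5 risen and 2 fallen regions of 34 (adjusted over the list alone, 5 and 2). With background scaling 0 rose and 3 fell, and the list's median went from 0.04 to -0.23. Regions at Tnf, Cxcl10 and Il12b changed by 0.53 (SE 0.13), 0.58 (SE 0.13) and 0.59 (SE 0.15) on the log2 scale, of which the first has Lta and the second Art3 as its nearest gene. Regions at Il1b and Cxcl3 fell by 0.49 (SE 0.15) and 0.54 (SE 0.11). In the immediate early and AP-1 list, 8 of 70 regions fell and 2 rose (adjusted over the list alone, 8 and 2; 15 and 0 with background scaling, 10 and 4 with the mouse as a block). The fallen ones included 4 regions at Fosb, by up to 0.64 (SE 0.08), 1 of them nearest to Rtn2, 2 at Fos, by up to 0.54 (SE 0.10), and 1 region at Dusp1, a MAP kinase phosphatase, by 0.84 (SE 0.10), while another region at Dusp1 rose by 0.56 (SE 0.15). Counts of called regions went the other way for this list, with 2.01 ± 0.23 regions per 1000 called after IL-1β against 1.81 ± 0.15 (SD, n = 8 each, exact permutation p = 0.0616, adjusted p = 0.163), and with equal-length lists the difference of 0.13 passed (exact permutation adjusted p = 0.0229). Regions at Slc7a11, a cystine transporter, and Txnrd1, a thioredoxin reductase, made up the 5 that fell of 30 in the heat shock and oxidative stress list, and 1 region at Srxn1 rose (adjusted over the list alone, 5 and 1; 8 and 0 with background scaling, 6 and 2 with the mouse as a block).

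Metabolic lists held risen regions at a few genes. The sterol synthesis list had 3 risen and 0 fallen of 28 regions (3 and 1 adjusted over the list alone; 3 and 2 with background scaling, 4 and 1 with the mouse as a block), among them the region at Mvd, an enzyme of the mevalonate pathway, at a log2 change of 0.89 (SE 0.09). The region at Mvd has Cyba as its nearest gene. Glycolysis had 4 risen and 1 fallen of 70 regions (adjusted over the list alone, 4 and 1; 1 and 3 with background scaling, 12 and 2 with the mouse as a block), with Pfkfb3, which makes an activator of glycolysis, at 0.93 (SE 0.15), and Slc2a1, a glucose transporter, at 0.70 (SE 0.12), while Pfkp fell by 0.45 (SE 0.09). The glucocorticoid response list had 5 risen and 3 fallen of 28 (5 and 5 adjusted over the list alone; 1 and 5 with background scaling, 5 and 5 with the mouse as a block), with Sgk1 at 1.04 (SE 0.16) and Klf9 at 0.65 (SE 0.09) against the falls at Tsc22d3 and Per1. The amino acid and ER stress list had 1 risen and 0 fallen of 20, the interferon list 1 and 2 of 29, with Irf7 falling by 0.64 (SE 0.09), and the cell cycle list 5 and 2 of 51 (limma; the same counts adjusted over each list alone). With background scaling the counts were 0 and 0, 0 and 4, and 0 and 4, and with the mouse as a block the amino acid and ER stress list had 2 risen and 0 fallen.

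Among marker lists, 0 of 34 stem cell regions changed (limma, 0 adjusted over the list alone), while 1 fell with background scaling and 1 rose with the mouse as a block. The mature neutrophil list had 6 risen and 1 fallen of 34, with Lcn2, which encodes an iron-binding granule protein, at 0.88 (SE 0.16), Mmp9 at 0.68 (SE 0.15) and Retnlg falling by 0.54 (SE 0.11). The granulocyte-monocyte progenitor list had 6 and 1 of 30, with Csf3r, the G-CSF receptor, at 0.59 (SE 0.16) and Ctsg falling by 0.58 (SE 0.14). Adjusted over the list alone, the counts were 8 and 1, and 7 and 2. Risen regions of other lists numbered 3 of 28 for monocyte and macrophage, 4 of 39 for erythroid, 1 of 22 for megakaryocyte, 1 of 15 for B cell, 2 of 21 for T and NK cell, 2 of 30 for dendritic cell and 1 of 19 for stroma and endothelium, with 0 fallen in each. Adjusted over each list alone these counts were the same, except 2 for B cell. With background scaling 1 region of the neutrophil list rose and 3 fell, and of the 9 other marker lists no region rose, while 3 fell in the progenitor list, 1 in the T and NK cell, 2 in the dendritic cell and 2 in the stroma list. With the mouse as a block, 10 rose and 1 fell in the neutrophil list, 9 and 2 in the progenitor list, 6 and 0 in the monocyte list, 3 and 0 in the megakaryocyte list, 2 and 0 in the B cell list and 1 and 1 in the stroma list. The mean over the neutrophil list was 0.08 ± 0.14 in IL-1β and -0.08 ± 0.33 in baseline libraries on the centred log2 scale (SD, n = 8 each), a difference that did not pass without pairing (exact permutation p = 0.155). Paired within mice it was 0.16, higher in 7 of 8 mice (exact sign-flip permutation p = 0.0234, adjusted p = 0.0469 over 4 lists), and 0.09 without diabetic mouse 4 (exact p = 0.0469, unadjusted). The progenitor list mean differed by 0.10 within mice, also higher in 7 of 8 (exact sign-flip permutation p = 0.0234, adjusted p = 0.0469; 0.07 without diabetic mouse 4, exact p = 0.0469, unadjusted). These paired tests were chosen after the unpaired values were seen and rest on median scaling. With background scaling the medians of these lists went from 0.15 to -0.12 and from 0.11 to -0.16. The median of all shared regions went from 0.03 to -0.24.

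The tests fixed before the data were examined asked where a peak was called or not. Fisher's exact test called 0 gained and 0 lost of 83972 regions after adjustment, with 921 gained and 2545 lost at unadjusted p below 0.05 and a smallest adjusted p of 0.204. At least 261 regions called in 8 of 8 against 0 of 8 libraries would have been needed before any passed, and 34 regions were called only after IL-1β in this way and 30 only at baseline. With the same 37543 peaks taken from every library, the unadjusted counts were 1239 gained and 837 lost, so the direction of the excess turned. The 8 gained regions with the highest −log10 q had as nearest genes Bhlhe40, a circadian and stress-responsive repressor, Fam207a, S100a3, D16Ertd472e (42987 bp away), Sik3, Tmbim6, Gm46963 and Itgam, the integrin αM subunit of myeloid cells. The 8 lost regions had as nearest genes Lmo1 (31378 bp away), Setd7, Amotl2, Map3k1, Dgat2, Rassf2, Usp46 (10775 bp away) and Bbs4. The gained region at Bhlhe40 spanned 108665506 to 108665992 on chromosome 6 and the lost region near Lmo1 109206387 to 109206783 on chromosome 7.

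Region counts per gene, scaled to the called regions of each library, gave 0 of 11392 genes after adjustment (exact permutation test, 1280 higher and 643 lower at unadjusted p below 0.05, smallest adjusted p 0.0637). List members at the smallest p that the permutations allow, 0.000408, were Zc3h12a (7.92 ± 0.72 against 5.52 ± 0.61 scaled regions, SD, n = 8 each), Ldha, the lactate dehydrogenase subunit (7.37 ± 1.08 against 5.12 ± 0.70), and Bag3, a chaperone partner (3.24 ± 0.59 against 0.95 ± 0.14). Of the 20 lists 0 passed adjustment. The lowest p-values were 0.00449 for sterol synthesis and 0.00816 for erythroid genes, each with an exact permutation adjusted p of 0.0707. NF-κB feedback had 2.03 ± 0.10 against 1.86 ± 0.12 regions per 1000 called (SD, n = 8 each, exact permutation p = 0.0147, adjusted p = 0.0735). With equal-length lists the erythroid difference went from 0.22 to 0.06 (exact permutation p = 0.589), and 9 lists passed (exact permutation tests). NF-κB feedback (difference 0.27) and B cell genes (0.14) had the lowest adjusted p, 0.00408 each. Immediate early and AP-1 genes (0.13) and sterol synthesis (0.10) were higher and interferon response was lower (-0.08), at an adjusted p of 0.0229 each. Stroma and endothelium (0.08) and glycolysis (0.15) passed at 0.0397, and mature neutrophil (0.21) and amino acid and ER stress genes (0.05) at 0.0426.

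The stimulated and baseline portions were also compared within each phenotype, to ask whether cells of diabetic mice respond differently. In control mice 444 regions rose and 242 fell, and in diabetic mice 546 rose and 160 fell (limma); with the mouse as a block the counts were 906 and 476, and 1038 and 336. With background scaling 20 rose and 173 fell in control mice (10.4% higher, against 64.7%), and 15 rose and 92 fell in diabetic mice (14.02% higher, against 77.3%). Leaving out 1 library of the same phenotype at a time gave 227 to 393 and 99 to 192 in control mice, and 219 to 722 and 89 to 376 in diabetic mice. Camera called NF-κB feedback in control mice (adjusted p = 0.0384) and in diabetic mice (adjusted p = 0.0163), and the mature neutrophil list in diabetic mice (adjusted p = 0.0300). With an estimated correlation none was called (adjusted p = 0.545, 0.378 and 0.805). The changes near Ankrd12 were 2.07 (SE 0.21) in control and 2.06 (SE 0.21) in diabetic mice, and those near Suco -1.72 and -1.63 (SE 0.18 each). Those at Msmo1 were 1.68 and 1.35 (SE 0.23 each), and those at Tsc22d3 -1.25 and -0.90 (SE 0.15 each). Of 686 regions called in control mice, 679 (99.0%) had the same sign in diabetic mice, and of 706 called in diabetic mice 704 (99.7%) had it in control mice. Both comparisons, which share no library, called 271 regions higher, where independent lists would share 9.71, and 84 lower, against 1.55. Their calls are not independent, since 1 fit gave both and estimated each region's variance from all 16 libraries. The expected numbers are therefore only a rough guide. Across regions, which are not independent replicates, the log2 changes correlated with r = 0.65.

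**Figure D3:**
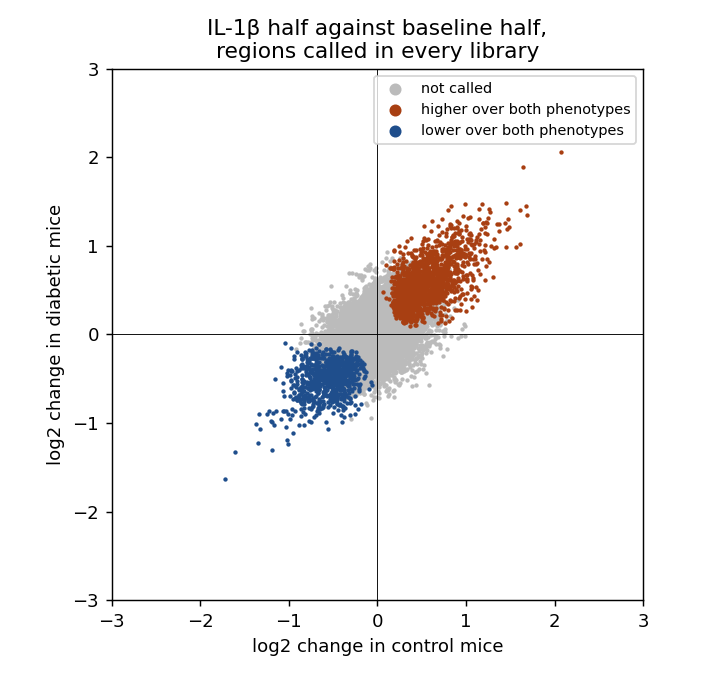
Log2 change of summit reads between the IL-1β and the baseline portion in control mice (horizontal) and diabetic mice (vertical) for the 24955 regions called in every library, coloured by the call over both phenotypes. Regions lie along the diagonal, with r = 0.65 across regions.

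The test of the difference itself called 0 of 24955 regions (limma, 416 at unadjusted p below 0.05, smallest adjusted p 0.9998). The change differed by -0.34 (SE 0.33) at Msmo1 and by 0.35 (SE 0.21) at Tsc22d3 between diabetic and control mice, and neither passed (limma adjusted p = 0.9998). Of the 20 lists 0 differed in their change of scaled region count (exact permutation tests, smallest p 0.114 for stroma and endothelium, adjusted p = 0.643), and camera called 0 lists (smallest adjusted p 0.28). The median SE of the difference per region was 0.24 on the log2 scale, against 0.12 for the change over both phenotypes, both from the fit without pairing by mouse. Recovery of a difference in response was not simulated, so the count of 0 does not show how large a difference could have been missed.

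Diabetic and control mice were compared at baseline, where the labels name diabetes as the contrast. Regions of mature neutrophil genes had a median log2 difference of -0.33 in diabetic libraries, those of granulocyte-monocyte progenitor genes -0.16 and those of erythroid genes 0.34. With background scaling, which moved the median shared region from 0.07 to -0.15, these values were -0.55, -0.38 and 0.12. Camera with a preset correlation called these 3 lists (adjusted p 1.55e-09, 0.000821 and 0.0120), and with an estimated correlation none (adjusted p 0.619, 0.619 and 0.808). The estimated correlations between regions were 0.44, 0.17 and 0.54, far above the preset 0.01. The p-values with the preset correlation therefore overstate the evidence for these lists. As a value per library, the neutrophil list mean was -0.24 ± 0.42 in diabetic and 0.08 ± 0.07 in control libraries (SD, n = 4 each, exact permutation p = 0.171). Without diabetic baseline replicate 1 the difference of -0.32 became -0.46 (exact permutation p = 0.0286, the smallest possible, unadjusted). Leaving out any other library gave an exact permutation p of 0.171 to 0.343. Diabetic baseline replicate 4 alone stood at -0.82, and without it the difference was -0.13 (exact permutation p = 0.343). Without that library the median over the list was -0.18 over the 47 regions called in the other 15 libraries, and -0.12 over the same 34 regions as before (camera on the 47 regions, adjusted p = 6.15e-08, adjusted p = 0.943 with an estimated correlation), and the erythroid and progenitor lists were not called (adjusted p 0.411 and 0.282). Their medians without it were 0.12 and -0.02, and 0.13 and -0.02 over the same regions as before. The erythroid means were 0.07 ± 0.46 and -0.23 ± 0.36 (SD, n = 4 each, exact permutation p = 0.314).

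**Figure D4:**
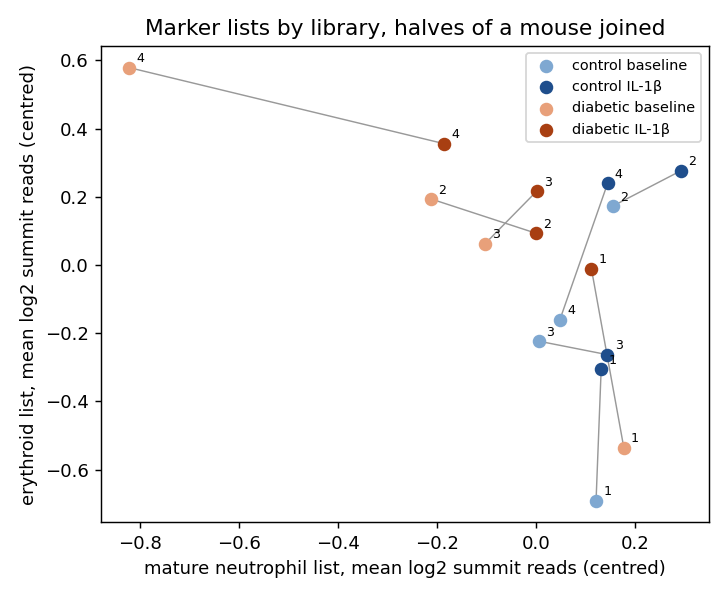
Mean log2 summit reads, centred on all libraries, over the mature neutrophil list (horizontal) and the erythroid list (vertical); points are libraries with their replicate number, and lines join both portions of a mouse. Diabetic baseline replicate 4 lies at -0.82 and 0.58, apart from the other libraries.

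No single region passed the test at baseline (limma, 0 higher and 0 lower of 24955, 2943 at unadjusted p below 0.05, smallest adjusted p 0.423). Adjusted over the list alone, 6 regions of the mature neutrophil list were lower and 1 of the B cell list was higher, and 0 passed in each of the other lists. Averaging both portions of each of the 8 mice also called 0 (limma, 2570 at unadjusted p below 0.05). Of the 20 lists 0 passed on scaled region counts (exact permutation test, lowest p 0.0857 for megakaryocyte and for stroma and endothelium, adjusted p = 0.686). Simulated 2-fold changes in this comparison were recovered for 88 of 100 regions and 1.5-fold changes for 20 of 100. By call, 20 regions were present in 4 of 4 diabetic and 0 of 4 control libraries and 214 the reverse, without a test per region. Of the 35 splits of these libraries, the real one included, 8 gave at least 234 such regions in both directions together (highest other 840). Chance can therefore not be excluded for these regions. The 20 included regions nearest to Spef2, Tiam1, Vgll4, Abcb1b, Tmtc1, Fam214a and Myo18a. The 214 included regions nearest to Clec2d (33692 bp away), with a mean −log10 q of 13.5 in control libraries, Cabin1, Asap1, Lpgat1 (23665 bp away), Snx3, Mapk6, Fam219b and Tmcc1. List length enters these counts, and equal-length lists gave 48 and 120.

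After IL-1β, the comparison of diabetic with control libraries asked whether the stimulated cells differ. The neutrophil list had a median log2 difference of -0.20, or -0.45 with background scaling, which moved the median shared region from 0.04 to -0.21 (camera adjusted p = 1.65e-07 with a preset correlation, adjusted p = 0.775 with an estimated correlation). Its mean per library was -0.02 ± 0.12 in diabetic and 0.18 ± 0.08 in control libraries (SD, n = 4 each, exact permutation p = 0.0286, the smallest these libraries allow, adjusted p = 0.343 over the 12 such tests). Control IL-1β replicate 2 stood highest at 0.29 and diabetic IL-1β replicate 4 lowest at -0.19. The difference of -0.20 became -0.16 without the former (exact permutation p = 0.0571, as without any 1 control library) and -0.14 without the latter (exact permutation p = 0.0286). No region passed (limma, 0 higher and 0 lower of 24955, 1086 at unadjusted p below 0.05, smallest adjusted p 0.970), and of the 20 lists 0 passed on scaled region counts (exact permutation test, lowest p 0.114 for sterol synthesis, adjusted p = 0.914). By call, 33 regions were present only in the 4 diabetic libraries and 35 only in the 4 control libraries, again without a test per region. Of the 35 splits of these libraries, 22 gave at least 68 such regions in both directions together (highest other 623), so chance cannot be excluded here either. The 33 included regions nearest to Cd28, Ablim1, Rec114, Atp10a, Tmem67 (31026 bp away), Cpa3, Rpl11 (36623 bp away) and Satb1. The 35 included regions nearest to Efcab2, Kif13b, 2810004N23Rik, Frmd6, Tkfc, Niban1, Cd69 (40107 bp away) and Creg1 (25885 bp away).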

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

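Every test in this part was chosen after the result was seen, except the covariate test of cell mix, the median without 1 library over the regions called in the other 15 and the relation between both lists over mice.

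Among 25 measures in 100 groups of 4 libraries, 8 values, from 4 libraries, stood far from the other 3 of their group, where chance gives about 1 in 20 groups. The measures share the same 4 groups of libraries, so these tests are not independent. All 8 were list means of log2 summit reads, centred on all libraries. Diabetic baseline replicate 4 stood apart in the monocyte and macrophage list (-0.29), the megakaryocyte list (-0.22) and the heat shock and oxidative stress list (0.28). Control IL-1β replicate 2, which has the shortest peak list, stood apart in the mature neutrophil list (0.29), the stroma and endothelium list (-0.19) and the glycolysis list (0.12). Control baseline replicate 2 stood apart in the granulocyte-monocyte progenitor list (-0.0492), and diabetic baseline replicate 1 in the glucocorticoid response list (0.0408).

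More regions lost than gained a call after IL-1β. With the same number of peaks from every library, lost over gained regions came to 0.676, so list length may account for the excess of losses. A general closing of chromatin stays open: scaled by background, the median shared region changed by -0.24, but signal over background also differs between libraries of the same group, and no measure here separates signal quality from closing.

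Summit reads differed after IL-1β at 2451 regions. With the neutrophil and erythroid list means as covariates, 78.1% of them stayed called with their direction, with a median size of 0.50 against 0.52. In all, 3096 regions were called with these covariates. The share kept was past the bound set in advance against a different mix of these precursors as the whole cause. Both means come from the same reads and include called regions, so they may follow the mix only in part. A different mix is therefore not excluded. Culture for 6 h without IL-1β cannot be told apart from IL-1β, since no library was cultured alone; the NF-κB feedback list had a camera p of 0.0154 with an estimated correlation (adjusted p = 0.308). An effect of IL-1β is therefore a hypothesis that these libraries leave open.

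The mature neutrophil list was lower in diabetic libraries at baseline. Without diabetic baseline replicate 4 its median was -0.18 over the 47 regions called in the other 15 libraries, between the bounds set in advance, and -0.12 over the 34 regions of the full comparison, also between them, so that the part of 1 library cannot be told apart from a difference between groups. Over the 8 mice the neutrophil and progenitor list means went together (rho = 0.738, permutation p = 0.0458, adjusted p = 0.0851 over 13 relations). The linear correlation was r = 0.949 (permutation p = 0.00417, adjusted p = 0.0108). Without the 2 mice farthest out r was 0.618, and the ranks given over all 8 mice correlated by 0.495. The strength of the relation therefore depends on those 2 mice. A different share of neutrophil precursors may account for the difference, although depletion of Gr1-carrying cells removes neutrophils and many of their late precursors; how complete it was in each sample is not known here, and diabetes stays open as an untested cause. The region overlapping S100a8, a gene that neutrophils use abundantly, held 69.5 ± 14.2 scaled reads in diabetic and 84.6 ± 4.24 in control baseline libraries (SD, n = 4 each; limma adjusted p = 0.423).

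Other splits of the same libraries were counted for each result, the real split included. Only the real split reached the unadjusted counts of regions after IL-1β (3466, 1 of 100 splits, highest other 2478) and of genes (1923, 1 of 100, highest other 1710). It was also alone in reaching the summit-read count over both phenotypes (2451, 1 of 100, highest other 131). A share of 1 of 100 is the lowest these splits allow, which makes a chance split unlikely but does not exclude it. The region count of 3466 rests on the lists as deposited, with 2545 lost against 921 gained, so list length may enter it. Splits that, like the real one, part both portions of every mouse gave the same shares for these results, 1 of 100, with highest others of 2242 regions, 1762 genes and 570 regions by summit reads. For summit reads in control mice (686; 1 of 35; highest other 7) and in diabetic mice (706; 1 of 35; highest other 9), only 8 splits part every mouse, too few for a share under 0.05, and the highest other of these was 0 in each. Over all 35 splits, chance cannot be excluded for regions present in all libraries of 1 group and none of the other: after IL-1β in control mice (752; 2 of 35; highest other 1210) and in diabetic mice (605; 3 of 35; highest other 808), and between diabetic and control mice at baseline (234; 8 of 35; highest other 840) and after IL-1β (68; 22 of 35; highest other 623). Of the 8 splits that part every mouse, the highest others were 356 in control and 156 in diabetic mice, so the splits with more regions kept both portions of a mouse together at least once. For summit reads between diabetic and control mice the real counts were 0, which 35 of 35 splits reach by construction, so these counts say nothing about chance. The highest other count at baseline was 701, and what sets the libraries of that split apart was not tested. The highest other count was 0 after IL-1β and 0 for the difference of the change.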

How the results depend on the processing

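The summit-read results compared in this part, with their alternatives, were chosen after the data were seen; the other alternatives were fixed earlier. Of 560 alternatives over 39 results, 437 were the same, 101 moved a count by over 1.5 times, 13 reversed and 9 passed a threshold not passed before. The same means that a tested value kept its direction and side of the threshold, or that a count stayed within 1.5 times. Many of the 437 were counts of 0 that stayed at 0. Where no construction is named, the cause was not tested. The 4 motif results and all alternatives at transcription start sites were not run. The mouse block passed the neutrophil and progenitor list means (exact sign-flip permutation p = 0.0234 each) and moved counts of regions within lists. Over both phenotypes, camera with the block called NF-κB feedback (adjusted p = 0.0253) and no other list, and none with an estimated correlation (lowest adjusted p 0.609). Of the other results compared here it changed no call but the counts given here. Depth limits uncalled regions, whose reads are unknown.

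With −log10 q of at least 5, the peak number difference was -7827 (exact permutation p = 0.0449) after IL-1β and -755 for diabetic against control after IL-1β. The gene-end share differences were then 3.41 (exact permutation p = 0.0392) and 0.0738. Covered length of the lists as deposited, taken in place of peak number, differed by -0.117 Mb for diabetic against control after IL-1β. Equal-length lists turned the gene-end share difference at baseline to -0.1196 and that of the change to 0.0834. Group-exclusive regions gained after IL-1β numbered 62 in control and 203 in diabetic mice with the stricter q, and 13 for diabetes at baseline. With equal-length lists, gained and lost regions were 323 and 286 in control mice, 133 were lost in diabetic mice, and diabetes gave 48 and 120 at baseline and 52 and 54 after IL-1β. With at least 3 of 4 against 0 of 4, which admits more regions by construction, they were 541 and 2399, 911 and 2000, 427 and 1039, and 321 and 352. With 50% of a region covered, 13 were gained for diabetes at baseline. For IL-1β against baseline, 9 of the 20 lists passed with the stricter q and 9 with equal-length lists. With 50% coverage 1 passed, and 1 with regions called in at least 4 libraries.

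For summit reads, background scaling gave 203 higher and 2343 lower after IL-1β, 20 higher in control mice, and 15 higher and 92 lower in diabetic mice. Regions called in at least 12 libraries, which are more, gave 1365 lower, and 441 in control mice. The mouse block gave 1294 lower, 906 higher and 476 lower in control mice, and 1038 and 336 in diabetic mice. Without diabetic mouse 4, 1531 were lower, with 1204 higher and 746 lower in control mice. Without control mouse 1, 259 were higher and 109 lower in control mice.

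Leaving out each library in turn gave peak number differences of -10861 to -5822 after IL-1β. For diabetes they were -8055 to -842 at baseline and -4506 to 5573 after IL-1β, and for the difference of the change 258 to 10229. Gene-end share differences were 1.5 to 3.22 after IL-1β, -0.241 to 1.63 and -2.10 to 1.34 for diabetes at baseline and after IL-1β, and -2.86 to 0.490 for the change. Group-exclusive regions gained and lost after IL-1β were 106 to 452 and 679 to 2000 in control mice, and 377 to 575 and 312 to 1297 in diabetic mice. For diabetes they were 26 to 355 and 241 to 735 at baseline, and 36 to 199 and 40 to 230 after IL-1β. For IL-1β against baseline, between 0 and 7 lists passed, the most without diabetic baseline replicate 1. For diabetes at baseline, diabetes after IL-1β and the difference of the change, 0 lists passed throughout. Summit reads gave 1144 to 2787 higher and 633 to 1657 lower after IL-1β, the most without diabetic baseline replicate 4. In control mice they gave 227 to 393 and 99 to 192, fewer without any 1 control library. In diabetic mice, with only diabetic libraries left out, they gave 219 to 722 (the most without diabetic baseline replicate 1) and 89 to 376 (the most without replicate 4). The counts of 0 for diabetes and for the difference stayed at 0.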

Other observations

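Peak number followed signal over background across libraries, a relation examined after the lists were seen. Over all 16 libraries r was 0.781 (permutation p = 0.00033, adjusted p = 0.0015 over 13 relations) and rho 0.850 (permutation p = 5.0e-05, adjusted p = 0.00052), and r was 0.833 without the 2 libraries farthest out. Within the 8 baseline libraries r was 0.572 (exact permutation p = 0.147) and rho 0.714 (exact permutation p = 0.0576), and within the 8 IL-1β libraries r was 0.857 (exact permutation p = 0.00541) and rho 0.905 (exact permutation p = 0.00456). With median reads over shared regions r was 0.867 over all libraries (permutation p = 7.0e-05, adjusted p = 0.00091) and rho 0.852 (permutation p = 8.0e-05, adjusted p = 0.00052), and r was 0.903 without the 2 libraries farthest out. Within baseline libraries this r was 0.803 (exact permutation p = 0.0109) and rho 0.881 (exact permutation p = 0.00724), and within IL-1β libraries r was 0.930 (exact permutation p = 0.000347) and rho 0.857 (exact permutation p = 0.0107). With background reads, which also reflect depth, r over all libraries was 0.154 (permutation p = 0.572) and rho 0.0382 (permutation p = 0.891).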
